A study of Drosophila melanogaster with 24 samples.

How the data were processed

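Gene expression was measured in adult whole females of Drosophila melanogaster with Affymetrix arrays, 1 array per line, in 8 groups of 3 replicate lines (24 arrays). The groups were an unselected control, lines selected for resistance to heat, cold, starvation, desiccation or knock-down, lines selected for longevity, and lines named constant 30. This name, read as a temperature in degrees, does not say whether the sampled females themselves were held at 30. Per the labels' protocols, 10 females per vial were homogenised and 5 micrograms of total RNA were labelled with biotin after oligo-dT priming. The labels call the lines biological replicates, so the p-values measure the spread between these lines. The kind of knock-down, the number of generations, the scan dates and the order of hybridisation are not given in the sources used here.

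The deposited values are on a log2 scale and were made by the authors with GCRMA, a background correction and normalization for probe sets, per the submitters' processing notes. Its version, its settings and whether all 24 arrays were processed together are not given in the sources used here. The log2 scale was read from the deposited values, which ran from -0.18 to 14.95 with array medians from 5.46 to 5.57. No background correction or normalization was added. The scanner files were not used here.

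The deposited table held 14010 probe sets and no missing values. The 44 control probe sets of the array maker were left out, which left 13966, and a probe set was tested when its log2 value was above 4 on at least 3 of the 24 arrays, whatever their group. This left 9023 probe sets. Gene names came from the platform annotation, with symbols updated through gene identifiers in the gene table of assembly Release 6, which was used for names alone. Of the 13966 probe sets, 12443 named a single gene (12394 with an updated symbol), 327 named several and 1196 named none. Among those tested the numbers were 8068, 222 and 733, with 7439 distinct genes. Counts are of probe sets. In gene lists and among named genes, a gene with several tested probe sets was represented by the one with the highest mean over all arrays.

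A linear model with 1 mean per group was fitted to the 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 16 residual and 3.6 prior degrees of freedom). Each of 7 regimes was compared with control, the mean of the 7 regimes was compared with control, 5 pairs of regimes were compared directly, and an F test asked for any difference between groups. P-values are two-sided and adjusted by Benjamini and Hochberg within each comparison. A probe set was called at an adjusted p under 0.05. At an unadjusted p under 0.05, chance alone gives 451 of the 9023 probe sets on average. Probe sets vary together, so counts can lie far from that average without a group difference. Errors of log2 changes are standard errors of the fit, with n = 3 lines per group.

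Gene names were chosen by rule. Among called probe sets that name 1 gene and whose 3 values in each group do not overlap, the rule took the 8 largest rises and the 8 largest falls, and the 6 largest of each among genes with a name other than a CG or CR number. For direct comparisons it took the 4 largest of each. List members were taken by their p, up to 4 per list and comparison, or for the count of their list. For 35 lists of genes, camera compared the members with all other genes at a preset correlation between genes of 0.01. Each list was also tested with a correlation estimated from the data and with fry, which asks whether the members move one way on balance. List p-values of the 7 comparisons against control were adjusted together, so the same smallest adjusted p can recur in several regimes. Those of the other comparisons were adjusted within each comparison. A list needed at least 3 tested genes. The design, the tests, the gene lists, the rule for names and most alternative settings were fixed before the data were examined.

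The similarity of regimes was set beside 100 simulations of unchanged groups that shared the 3 control arrays. The fit was tested on simulated data for heat selected against control, over 9023 probe sets in 20 draws with 200 changed probe sets each. It recovered 72.1% of changes of 0.5 on the log2 scale, 97.2% of changes of 1 and 97.9% of changes of 2, and 4.48% of its calls were false. Lists of 30 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 20 of 20 draws, and unshifted lists in 1. The noise was drawn for each gene apart, so camera was not tested on lists whose genes vary together. With nothing changed, constant 30 against control gave 0.15 calls per draw. These rates hold for noise that is independent between probe sets. They do not give limma's error rate on the real arrays, where probe sets vary together. There, another split of the constant 30 and control arrays gave 38 calls.

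The alternative settings fixed then were no filter, a filter at 6, quantile normalization, median centring, a pseudocount of 16 on the linear scale, limma with trend and robust settings (which use statmod 1.5.0), array weights, a fit of the compared groups alone, the replicate number as a block, adjustment over the 7 comparisons together, a threshold of 1 on the absolute log2 change, the mean over the probe sets of a gene in the lists, and leaving out each array in turn. Alternatives with a covariate for RNA quality, and with the other 6 regimes in place of control, were added after the data were seen. The number of arrays limits the precision, and 3 lines against 3 make 10 splits, too few for an exact permutation p under 0.05.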

Results

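The 24 arrays measured transcript levels in whole females of 8 groups of Drosophila lines, 3 lines per group, and asked how selection for different kinds of stress resistance changed expression. Array medians lay between 5.46 and 5.57 on the log2 scale, and 8544 to 9071 probe sets per array were above 4. Arrays of a group correlated at 0.986 to 0.995 and arrays of different groups at 0.978 to 0.996, with medians of 0.992 within and 0.992 between groups. The median residual SD of a probe set was 0.12. The first principal component held 21.9% of the variance, with heat selected replicates 1 and 2 at 18.5 and 22.1, heat selected replicate 3 at 6.47 and knock-down selected replicate 2 at 14.8.

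**Figure D1:**
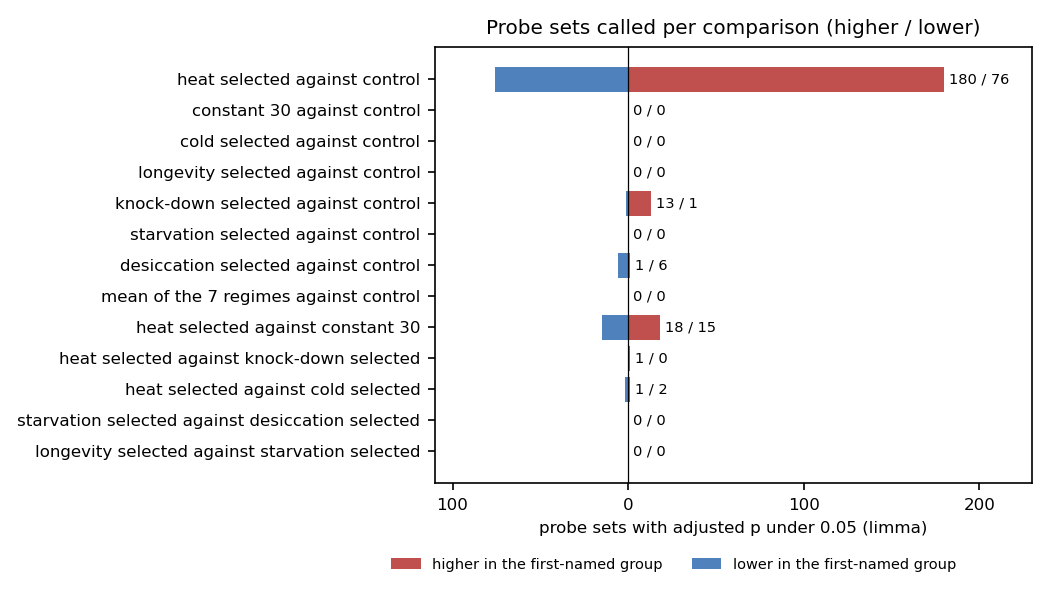
Probe sets called by limma at an adjusted p under 0.05 (horizontal axis, number of probe sets) in each comparison, with higher calls to the right and lower calls to the left. Heat selected against control had 180 higher and 76 lower, and 4 of the 7 regimes had 0 against control.

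Heat selected females had the most called genes of any regime, among them genes of muscle, eye and eggshell. The muscle genes Mlc1 (myosin light chain), Tm2 (tropomyosin), up (troponin T), sls (the titin-like protein of the sarcomere) and Zasp52 (a Z disc protein) rose, as did RyR, the channel that releases calcium in muscle. Lsp2, a larval serum storage protein made by the fat body, fell more than any other called gene. Femcoat, Cp16 and Cp19, which encode proteins of the eggshell, fell, and so did srp, the GATA factor of the fat body and blood cells. Ctr1B, a copper importer, and inaD and Gbeta76C of the light response rose.

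Heat selected against control gave 256 called probe sets, 180 higher and 76 lower, which name 213 single genes (1846 at an unadjusted p under 0.05). Of these, 29 changed by at least 1 on the log2 scale, 16 up and 13 down. The values of the groups did not overlap in 23.4% of all tested probe sets, which chance gives for 10% on average. Probe sets vary together, so the share can lie far from that average without a group difference. It was 7.0% for starvation against desiccation selected, and the share is not a test. Lsp2 fell from 9.60 ± 1.10 (SD, n = 3) to 5.55 ± 0.91, a log2 change of -4.05 ± 0.78 (SE, adjusted p = 0.0199). The Lsp2 means of the other 6 regimes also lay below control, so the difference of heat selected from them was smaller. Knock-down selected replicate 2, at 5.94, lay inside the heat selected range of 4.57 to 6.37. Femcoat changed by -1.72 ± 0.34 (adjusted p = 0.0199), Cp19 by -1.18 ± 0.28 (adjusted p = 0.0339), Cp16 by -1.11 ± 0.28 (adjusted p = 0.0412) and srp by -1.07 ± 0.18 (adjusted p = 0.0130). Muc12Ea, a mucin, fell by 1.08, and the uncharacterised CG15571, CG18088, CG13113, CG13083 and CG13084 fell by 1.61, 1.38, 1.18, 1.18 and 1.15. CG1648 rose most, by 1.62 ± 0.41 (adjusted p = 0.0407), followed by CG8329, a serine protease, with 1.46 ± 0.28 (adjusted p = 0.0199). Mlc1 rose by 1.17 ± 0.30 (adjusted p = 0.0425), RyR by 1.03 ± 0.25 (adjusted p = 0.0382), Tm2 by 0.97 ± 0.21 (adjusted p = 0.0294) and Ctr1B by 0.94 ± 0.22 (adjusted p = 0.0339). The called probe sets of Zasp52 rose by 0.92, 0.77 and 0.93. CG42319 rose by 1.25, while its other probe set, at 0.09, was not called, and CG14109, CG3088, CG14757 and fau rose by 1.21, 1.15, 1.04 and 0.97. Leaving out 1 array moved the 256 calls to 0 without control replicate 1 or heat selected replicate 2, 1 without control replicate 2, 23 without heat selected replicate 1, 517 without control replicate 3 and 591 without heat selected replicate 3. The count was 0 in a fit of these 6 arrays alone, 144 with no filter (140 of them among the 256), 12 when adjusted over the 7 comparisons together and 1 with a covariate for RNA quality, added after the data were seen. That covariate was lower on every heat selected array than on every control array, so it partly stands for the group itself.

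**Figure D2:**
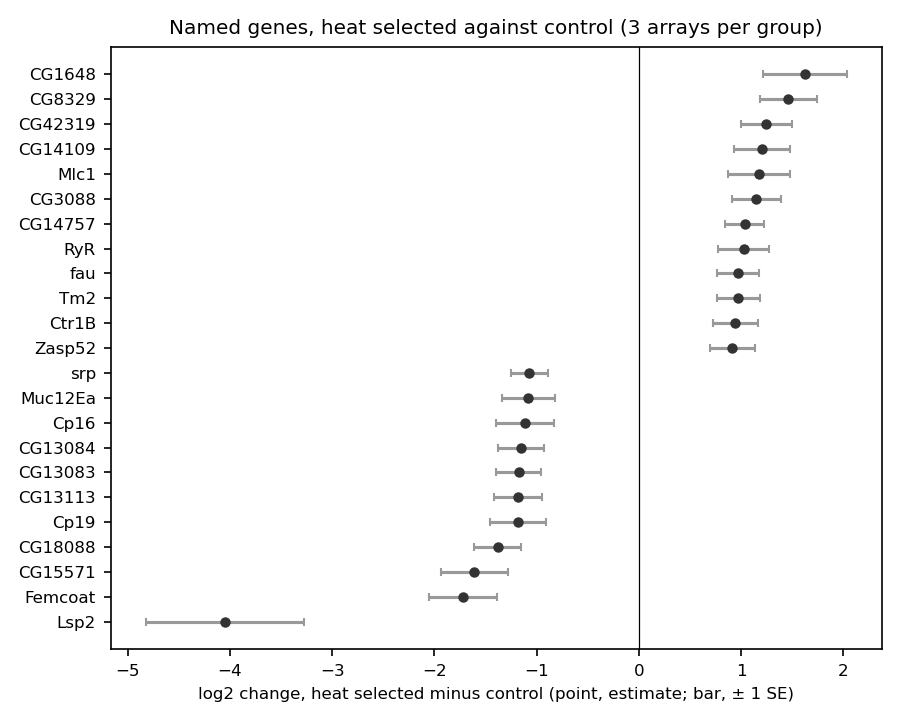
Log2 change of the genes named by rule in heat selected against control lines (horizontal axis; points, estimates; bars, 1 SE; 3 lines per group). Lsp2 lies farthest from 0, at -4.05, and the largest rise is that of CG1648, at 1.62.

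Among the fixed gene lists, camera placed 7 above and 2 below the other genes in heat selected females at its preset correlation. None of the 9 was called with an estimated correlation (adjusted p = 0.588 with an estimated correlation for each), so these camera calls rest on the preset value. Of 25 muscle genes the median change was 0.69, and 6 rose (20 adjusted over the list alone): Mlc1, Tm2, Zasp52, up (0.91), sls (0.69) and Zasp66 (0.66). The flight muscle genes Act88F, Mlp60A and fln, at 1.79, 1.49 and 1.44, passed only when adjusted over the list alone, and the enzymes Gpdh1 (-0.28) and arg (-0.22) fell there. The 15 eye and phototransduction genes had a median of 0.52, and 5 rose (8 adjusted over the list alone), among them Gbeta76C by 0.87, inaD by 0.78, Arr1 by 0.72 and Arr2 by 0.65. The 55 genes of oxidative phosphorylation had a median of 0.33, and 11 rose (46 adjusted over the list alone), with ND-39 at 0.55 and UQCR-6.4 at 0.53. SdhD and Idh3b, of 10 genes of the tricarboxylic acid cycle with a median of 0.38, rose by 0.49 and 0.48 (7 adjusted over the list alone). Of 34 cytosolic ribosomal proteins 5 rose (13 adjusted over the list alone), with RpL3 at 0.32 and a list median of 0.13. The neuronal genes Ddc, futsch and nSyb rose by 0.64, 0.51 and 0.43 (5 of 8 adjusted over the list alone). Maltases and amylases, which digest sugars, had a median of 0.41 with 0 of 13 called over all genes and 4 adjusted over the list alone, Mal-A3, Mal-A4, Mal-A8 and Mal-B2. List scores, the mean log2 value of a list per array, differed between the heat selected lines. On replicates 1, 2 and 3 muscle was at 9.63, 9.56 and 9.07 (control arrays 8.50, 8.63 and 9.04), eye at 6.84, 6.83 and 6.55 (control 6.22, 6.21 and 6.57) and maltases at 8.81, 8.39 and 8.19 (control 7.82, 8.13 and 8.21). Replicate 3 thus lay beside control replicate 3 in all of these lists. The maltase median was 0.25 and not called without heat selected replicate 1, and the eye median was 0.29 without control replicate 2.

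The eggshell list of 12 genes had a median of -0.69 in heat selected females, with all 12 below 0, and Femcoat alone fell (1 adjusted over the list alone). That list does not hold the chorion genes with plain numbers. Beside Cp16 and Cp19, the probe sets of Cp18, Cp38, Cp36 and Cp15, chosen after their values were seen, were at -1.06, -0.62, -0.50 and -0.49 and were not called. Of 28 germ line genes, with a median of -0.12, CycE fell by 0.58 (3 adjusted over the list alone, with orb and pgc). Yolk proteins had a median of -0.30 and were not called (0 over all genes, 1 adjusted over the list alone, Yp3 at -0.36). The heat shock proteins and chaperones, 15 genes with a median of 0.09, were not called either, and 0 passed over all genes (1 adjusted over the list alone, l(2)efl at 0.81, adjusted p = 0.0562 over all genes). Single called members of other lists were FASN2 (0.85), Ugt36D1 (0.91), Irk3 (0.80), Tps1 (0.53), PGRP-LA (0.51), Tl (-0.48), bmm (-0.31) and Cyp6a22 (-0.29). At the preset correlation the adjusted p-values of the 9 lists by camera ran from 7.36e-21 for oxidative phosphorylation to 0.00672 for maltases. They were 0.000622 for eggshell, 2.45e-09 for muscle and 0.00218 for germ line. With an estimated correlation none of these calls held (smallest adjusted p = 0.588). Of the same lists fry called 3, the eye, neuronal and ribosomal lists (adjusted p = 0.0468 for each). Eggshell scores were 9.08, 9.17 and 10.46 on heat selected replicates 1, 2 and 3 and 10.55, 10.29 and 10.22 on the control arrays, and the eggshell median was -1.18 without heat selected replicate 3. The germ line median was -0.07 without heat selected replicate 1. The 3' minus 5' difference of the array's control probe sets, a measure of RNA quality, was 1.62, 1.34 and 1.68 on the heat selected arrays and 1.74, 1.69 and 1.82 on the control arrays. A larger difference means less signal at the 5' end relative to the 3' end. Every heat selected value lay below every control value.

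**Figure D3:**
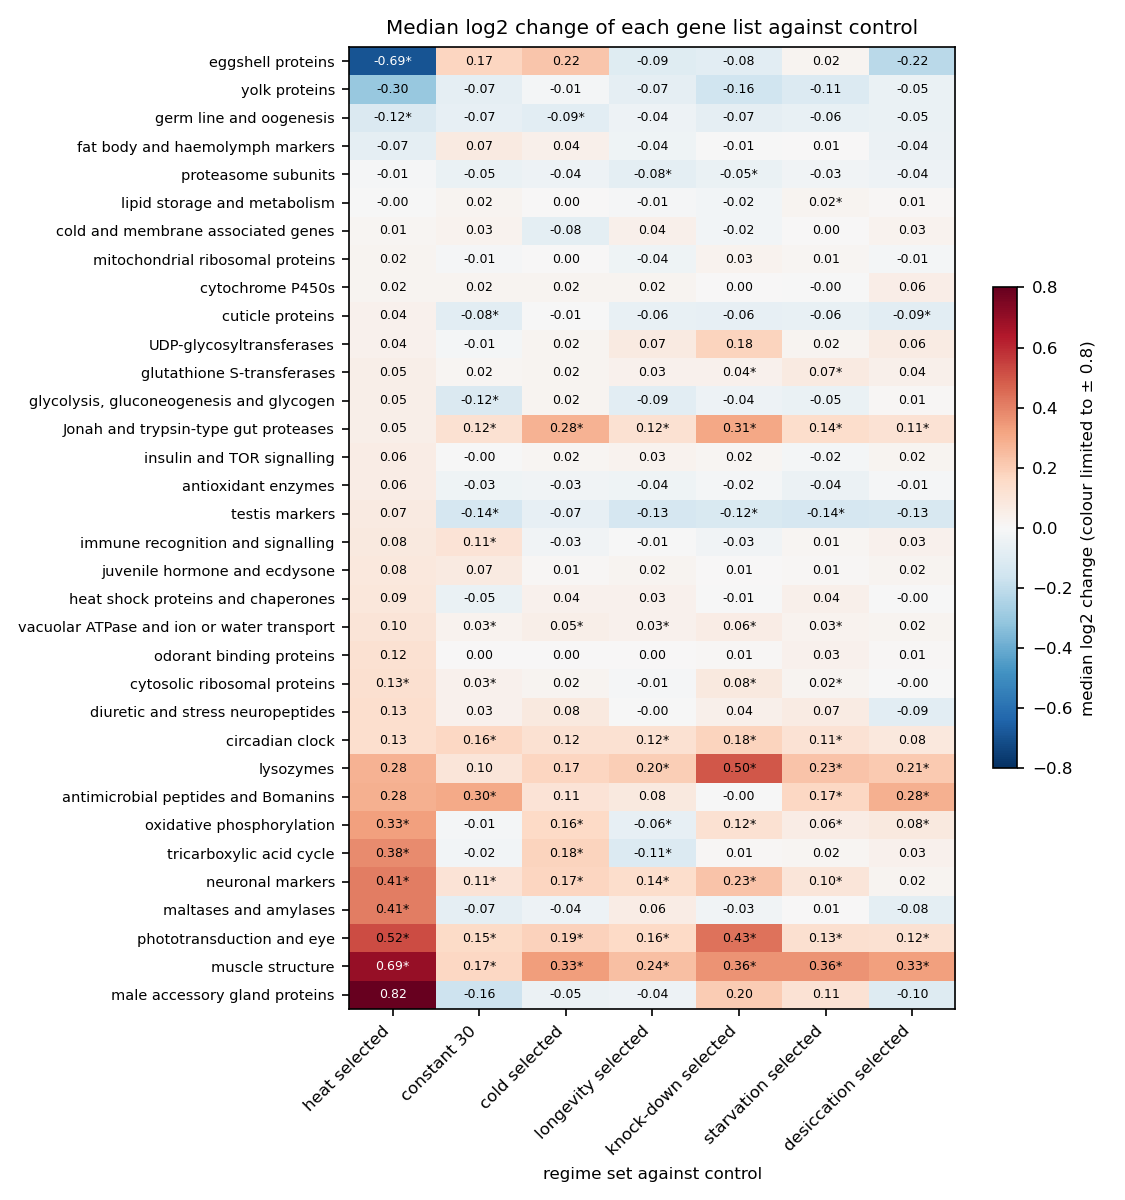
Median log2 change (colour and printed value) of the genes of each list (vertical axis) in each of the 7 regimes against control (horizontal axis), with an asterisk where camera called the list at the preset correlation. Muscle and phototransduction lists were called higher in 7 of 7 regimes, a call lost in each with an estimated correlation (smallest adjusted p = 0.588), and the eggshell median was -0.69 in heat selected lines.

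In knock-down selected females, Ctr1B, GstE2 and CG17752 rose most among the genes named by rule. Ctr1B, the copper importer, rose by 1.46 ± 0.22 (adjusted p = 0.0205), and GstE2, a glutathione S-transferase, by 1.14 ± 0.19 (adjusted p = 0.0251). CG17752, a predicted organic ion transporter, rose by 1.21 ± 0.21 (adjusted p = 0.0324). Ank2, a neuronal ankyrin, rose by 0.80 ± 0.15 (adjusted p = 0.0328) on 1 probe set, while its others, at -0.15 and -0.10, were not called. Srr (serine racemase), Six4 (a homeobox factor of muscle and gonad) and REPTOR-BP (a partner in the TOR response) rose by 0.80, 0.68 and 0.52, CG5002 and CG43673 by 0.91 and 0.68, and Usp14, a deubiquitinase, fell by 0.35 (adjusted p = 0.0484). In all, 14 probe sets were called, 13 higher and 1 lower (939 at an unadjusted p under 0.05). Leaving out control replicate 1, control replicate 2, knock-down selected replicate 2 or knock-down selected replicate 3 gave 0 calls and leaving out control replicate 3 gave 237, while the fit of these 6 arrays alone gave 0, array weights 54 and adjustment over the 7 comparisons 5.

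In knock-down selected females camera called 12 lists (6 without control replicate 1), 0 with an estimated correlation (smallest adjusted p = 0.588 with an estimated correlation), and fry 0. Lysozymes, which digest bacterial walls in the gut, had a median of 0.50, with 0 of 7 called over all genes and 4 adjusted over the list alone, LysP (1.03), LysB, LysC and LysD. Eye genes had a median of 0.43 (8 adjusted over the list alone), muscle genes 0.36 (3 adjusted over the list alone) and gut proteases 0.31. Knock-down selected replicate 2 had the highest muscle and eye scores of its group, 9.34 and 6.79, against 8.58 and 6.59 on replicate 1 and 9.03 and 6.64 on replicate 3. Without it the muscle median was 0.18 and the eye median 0.22. Without knock-down selected replicate 1 the muscle median was 0.58 and that of gut proteases 0.17. The 3' minus 5' difference of replicate 2 was 1.50, against 1.76 and 1.70. Of 26 glutathione S-transferases, with a median of 0.04, GstE2 rose (5 adjusted over the list alone, with GstE3 at 0.92, GstE5 at 0.77 and GstE12 at 0.41). That median was -0.018 with no filter and -0.027 without knock-down selected replicate 1.

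Desiccation selected females had less transcript of CycT, the cyclin of the kinase that releases paused RNA polymerase, of egh, a glycosyltransferase for membrane glycolipids, and of Scamp, a protein of secretory vesicles. CycT changed by -0.55 ± 0.08 (adjusted p = 0.00217), egh by -0.51 ± 0.07 (adjusted p = 0.00156) and Scamp by -0.46 ± 0.07 (adjusted p = 0.00435). CG17919 rose by 0.47 ± 0.09 (adjusted p = 0.0312). CG2926, at -0.89 ± 0.12 (adjusted p = 0.00165), and CG30389, at -0.52 ± 0.09 (adjusted p = 0.0191), lie outside the rule for names and were chosen after their values were seen. Other probe sets of these genes did not move alike: those of egh, CG2926 and CG30389 were at -0.10, 0.05 and 0.05 and were not called. The group means of CG2926 also fell along the order of the groups in the deposited table, from 9.58 in control to 8.69 in desiccation selected, and those of Scamp from 8.10 to 7.65. All 7 called probe sets, those of egh, CycT and CG17919 included, had a slope along that order, in which control is first and desiccation selected last. In all 7 probe sets were called, 1 higher and 6 lower (647 at an unadjusted p under 0.05). The count was 4 without control replicate 1, 42 without control replicate 3, 26 with array weights and 0 in a fit of these 6 arrays alone. Among lists in desiccation selected females, muscle had a median of 0.33, antimicrobial peptides 0.28 (scores of 8.49, 7.82 and 8.80 on replicates 1, 2 and 3), lysozymes 0.21, gut proteases 0.11 and cuticle proteins -0.09, with TwdlD at -0.39 the 1 that passed adjusted over the list alone. Camera called 7 lists (4 without control replicate 1 or control replicate 2, 3 without desiccation selected replicate 3, 11 without desiccation selected replicate 1), 0 with an estimated correlation (smallest adjusted p = 0.588 with an estimated correlation), and fry 0. The lysozyme median was -0.000453 and the antimicrobial median 0.06 without desiccation selected replicate 3. Gut proteases were at 0.02 without control replicate 2, cuticle proteins at -0.05 and muscle at 0.22 without control replicate 1, and muscle at 0.50 without control replicate 3.

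**Figure D4:**
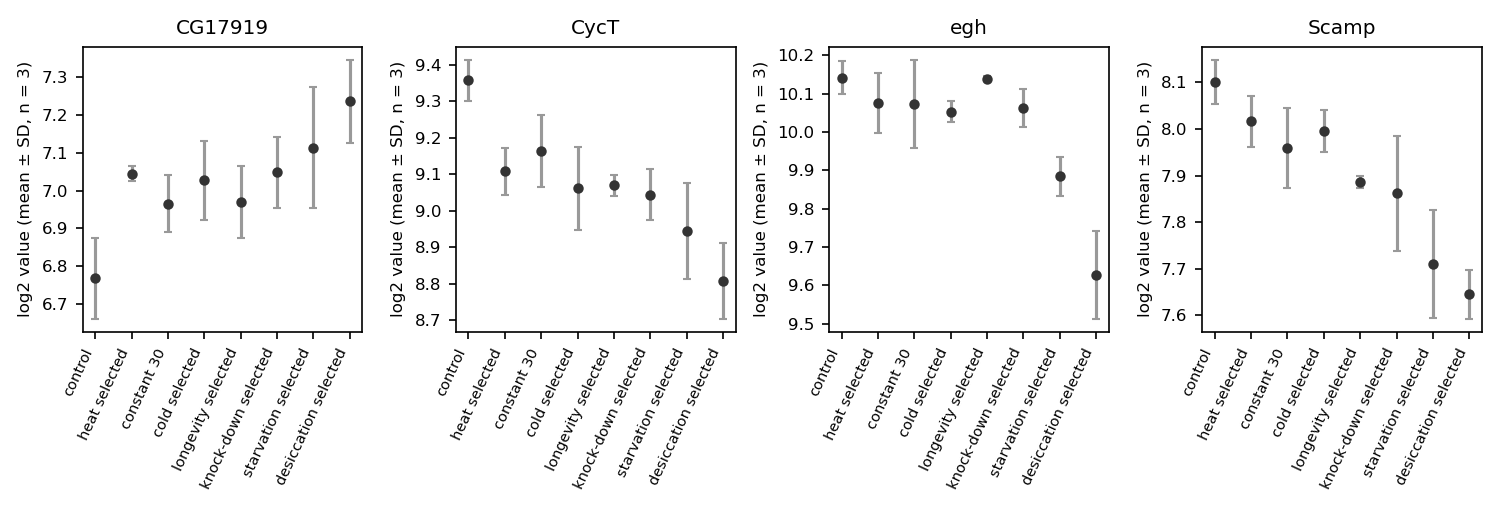
Log2 values (vertical axes; points, means; bars, SD; 3 lines per group) of CG17919, CycT, egh and Scamp, the genes named by rule in desiccation selected against control lines, in the 8 groups in the order of the deposited table (horizontal axis). Scamp had a group mean of 8.10 in control and 7.65 in desiccation selected lines, and CG17919 had 6.77 and 7.24.

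Females of the constant 30 lines differed from control in no called probe set. Camera placed immune, clock and eye lists higher, but 0 of its 12 list calls held with an estimated correlation (smallest adjusted p = 0.588 with an estimated correlation). Def and Drs, secreted antimicrobial peptides, were at 2.07 and 0.67 and passed only adjusted over the list alone (0 of 15 over all genes, 2 adjusted over the list alone), with a list median of 0.30. The antimicrobial list score was 9.37 on constant 30 replicate 3, 8.50 on replicate 1 and 7.86 on replicate 2, and 7.69, 8.24 and 7.98 on the control arrays. Clk, the transcription factor of the circadian clock, was at 0.55 (1 adjusted over the list alone), and Arr2, inaC, Gbeta76C and rdgA of the eye passed adjusted over the list alone (4). Lower lists were testis markers at -0.14, glycolysis at -0.12 (1 adjusted over the list alone, AGBE at -0.34) and cuticle proteins at -0.08. The antimicrobial median was 0.01 without control replicate 1, that of glycolysis -0.07 without constant 30 replicate 3 and that of cuticle proteins -0.05 without control replicate 3. Limma called 0 probe sets (630 at an unadjusted p under 0.05, smallest adjusted p = 0.359), 3 without constant 30 replicate 1 and 49 without control replicate 3. Fry called 0 lists, and camera gave 5 without control replicate 1, 4 without control replicate 2, and 7 without constant 30 replicate 1 or constant 30 replicate 3.

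Cold selected females had gut protease, muscle and mitochondrial lists above control at camera's preset correlation. Of its 8 list calls, 0 held with an estimated correlation (smallest adjusted p = 0.588 with an estimated correlation). The median of the 27 Jonah and trypsin-type proteases was 0.28, of muscle 0.33, of the tricarboxylic acid cycle 0.18 and of oxidative phosphorylation 0.16, and germ line genes had a median of -0.09; 0 members passed over all genes or adjusted over the list alone. Oxidative phosphorylation scores were 10.13, 9.90 and 10.21 on cold selected replicates 1, 2 and 3 and 9.88, 9.87 and 10.01 on the control arrays, so replicate 2 lay inside the control range. The median of that list was 0.26 without cold selected replicate 2 and 0.095 without cold selected replicate 3, and that of the tricarboxylic acid cycle 0.28 and 0.11. The muscle median was 0.55 without control replicate 3 and the germ line median -0.05 without control replicate 2. Limma called 0 probe sets (713 at an unadjusted p under 0.05, smallest adjusted p = 0.425) and 35 without control replicate 3. Camera called 5 lists without control replicate 1 or control replicate 2, and fry 0.

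Longevity selected females had lysozyme, gut protease and muscle lists higher and the tricarboxylic acid cycle, proteasome and, through 1 line, oxidative phosphorylation lists lower at camera's preset correlation. Of its 10 list calls, 0 held with an estimated correlation (smallest adjusted p = 0.588 with an estimated correlation). Lysozymes had a median of 0.20 (LysP, at 0.86, the 1 that passed adjusted over the list alone, 0 over all genes), gut proteases 0.12 and muscle 0.24. The tricarboxylic acid cycle was at -0.11, proteasome subunits at -0.08 and oxidative phosphorylation at -0.06. Oxidative phosphorylation scores were 9.70, 9.93 and 9.91 on longevity selected replicates 1, 2 and 3 and 9.88, 9.87 and 10.01 on the control arrays. Without longevity selected replicate 1 that median was -0.01 and not called, and without longevity selected replicate 2 it was -0.11 and the tricarboxylic acid cycle at -0.17. Lysozymes were at 0.10 without control replicate 2 and 0.34 without control replicate 3, gut proteases at 0.03 without control replicate 1 and 0.25 without control replicate 3, and muscle at 0.11 and 0.37 without the same arrays. Limma called 0 probe sets (717 at an unadjusted p under 0.05, smallest adjusted p = 0.305) and 37 without control replicate 3. Camera called 6 lists without control replicate 2 and 5 without longevity selected replicate 3, and fry 0.

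Starvation selected females had muscle, lysozyme and antimicrobial peptide lists higher at camera's preset correlation, with medians of 0.36, 0.23 and 0.17, and gut proteases at 0.14. Camera called 13 lists there, 0 with an estimated correlation (smallest adjusted p = 0.588 with an estimated correlation). The antimicrobial score was 8.91 on starvation selected replicate 2, 7.88 on replicate 1 and 7.98 on replicate 3, and 7.69, 8.24 and 7.98 on the control arrays. The antimicrobial median was 0.01 without starvation selected replicate 2 and 0.39 without replicate 1. Lysozymes were at 0.11 and gut proteases at 0.03 without control replicate 2, and muscle at 0.19 without control replicate 1. Genes of lipid storage and metabolism had a median of 0.02, and Npc2b, a sterol binding protein, was at 0.69 (0 over all genes, 1 adjusted over the list alone). That lipid median was -0.00331 without control replicate 1 and -0.032 without starvation selected replicate 3. Limma called 0 probe sets (831 at an unadjusted p under 0.05, smallest adjusted p = 0.0673), 177 with array weights, 4 with median centring, 83 without control replicate 3 and 16 without starvation selected replicate 1. Camera called 7 lists without control replicate 1 or control replicate 2, and fry 0.

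Over the 7 regimes, camera at the preset correlation called muscle and eye lists higher in every one, with medians from 0.17 to 0.69 and from 0.12 to 0.52. None of the list calls over regimes held with an estimated correlation (smallest adjusted p = 0.588 with an estimated correlation). Gut proteases and neuronal markers were called higher in 6 regimes, oxidative phosphorylation in 5 (and lower in longevity selected), transporters with the vacuolar ATPase in 5, and lysozymes, clock genes and cytosolic ribosomal proteins in 4. Antimicrobial peptides were called higher in 3, glutathione S-transferases in 2, the tricarboxylic acid cycle in 2 (and lower in longevity selected), and immune recognition genes, lipid genes and maltases in 1. Testis markers were called lower in 3 regimes and proteasome subunits, germ line genes and cuticle proteins in 2, and eggshell and glycolysis genes in 1. Lists called in no regime had median changes from -0.30 to -0.01 for yolk proteins, -0.05 to 0.09 for heat shock proteins, -0.04 to 0.06 for antioxidant enzymes, -0.01 to 0.18 for UDP-glycosyltransferases, -0.02 to 0.06 for insulin and TOR signalling, -0.04 to 0.03 for mitochondrial ribosomal proteins, -0.07 to 0.07 for fat body markers and -0.16 to 0.82 for male accessory gland proteins. The ranges were -0.09 to 0.13 for diuretic and stress neuropeptides, -0.08 to 0.04 for cold and membrane genes, 0.00 to 0.12 for odorant binding proteins, 0.01 to 0.08 for hormone genes and -0.00416 to 0.06 for cytochrome P450s, and 0 of the Turandot stress peptides were tested.

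For the mean of the 7 regimes against control, muscle genes had a median of 0.34 (0 over all genes, 5 adjusted over the list alone), eye genes 0.22 (0 over all genes, 8 adjusted over the list alone), clock genes 0.16 and germ line genes -0.07. Camera called 12 lists, 0 with an estimated correlation (smallest adjusted p = 0.235 with an estimated correlation). Limma called 0 probe sets (982 at an unadjusted p under 0.05, smallest adjusted p = 0.0598), 267 without control replicate 3, 8 without longevity selected replicate 1, 3 without heat selected replicate 3, knock-down selected replicate 1 or starvation selected replicate 1, and 1 without control replicate 1. Array weights gave 118, quantile normalization 11 and a filter at 6 gave 6.

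The F test for any difference between groups called 5 probe sets. They name egh, CG2926 and Scamp, lowest in desiccation selected females, Cdk5, a neuronal kinase, and CG15412. The other probe sets of egh and CG2926 were not called, and were at -0.10 and 0.05 in desiccation selected against control. The called probe sets of egh, CG2926 and Scamp also had a slope along the order of the groups in the deposited table. Cdk5 had a mean of 6.69 in heat selected and 7.19 in control females, and CG15412 of 4.53 and 4.04. The adjusted p of limma's F test was 0.00956 for egh and CG2926, 0.0139 for Cdk5, 0.0206 for CG15412 and 0.0388 for Scamp (1389 probe sets at an unadjusted p under 0.05). CG15412 lay near the lower limit of 4 used as the filter. The 5 calls became 78 without control replicate 3, 15 without heat selected replicate 3, 10 without knock-down selected replicate 1, 3 without desiccation selected replicate 2, and 2 without heat selected replicate 2 or desiccation selected replicate 3. Array weights gave 48 and quantile normalization 9.

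Heat selected and constant 30 females, the groups whose labels both name heat or a raised temperature, differed directly in 33 probe sets, 18 higher and 15 lower. ND-75, of complex I, rose in heat selected against constant 30 by 0.69 ± 0.14 (adjusted p = 0.0382), and srp, the GATA factor, fell by 1.17 ± 0.18 (adjusted p = 0.0138). Cpr47Ef, a cuticle protein, muc, an acyltransferase of the pyruvate dehydrogenase complex, and CG14757 rose by 0.65, 0.65 and 1.03, and pst (pastrel, linked to resistance to viruses), CG13083 and CG18088 fell by 0.93, 1.04 and 1.15. Eggshell genes had a median of -0.88 (0 over all genes, 1 adjusted over the list alone), oxidative phosphorylation 0.35 (2 rose, 46 adjusted over the list alone), the tricarboxylic acid cycle 0.43 (1 rose, 6 adjusted over the list alone), muscle 0.49 (0 over all genes, 19 up adjusted over the list alone) and maltases 0.56. Eggshell scores were 11.09, 9.74 and 10.54 on constant 30 replicates 1, 2 and 3, against 9.08, 9.17 and 10.46 on the heat selected arrays. Camera called 12 lists, 0 with an estimated correlation (smallest adjusted p = 0.498 with an estimated correlation). At an unadjusted p under 0.05 there were 2088, and median centring gave 14 higher and 23 lower. Leaving out heat selected replicate 2 gave 0, heat selected replicate 1 20, constant 30 replicate 1 or replicate 2 7, constant 30 replicate 3 1 and heat selected replicate 3 430. A filter at 6 gave 104, trend and robust settings 141, quantile normalization 71, array weights 13 and the fit of the 6 arrays alone 2. With the covariate for RNA quality, added after the data were seen, 0 were left. The replicate number as a block gave 125 higher and 93 lower. Fry called 3 lists, the tricarboxylic acid cycle and oxidative phosphorylation (adjusted p = 0.0314 for each) and the male accessory gland list (adjusted p = 0.00732). Of the 4 tested members of the latter, Acp1 and Acp65Aa are adult cuticle genes, and the list score was 6.78 on heat selected replicate 1 but 4.49 and 4.10 on replicates 2 and 3.

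Heat selected against knock-down selected females differed in CG15412, uncharacterised, which rose by 0.45 ± 0.07 (adjusted p = 0.0411), the 1 call (1333 at an unadjusted p under 0.05). Its means of 4.53 and 4.07 lay near the filter limit of 4, so the size of the change is uncertain. Eggshell genes had a median of -0.61, maltases of 0.43 and gut proteases of -0.17. Eggshell scores were 9.08, 9.17 and 10.46 on heat selected replicates 1, 2 and 3 and 10.53, 10.05 and 10.03 on the knock-down selected arrays, so that heat selected replicate 3 was not lower than 2 of these. Camera called 10 lists, 0 with an estimated correlation (smallest adjusted p = 0.537 with an estimated correlation). The 1 call became 0 with a filter at 6, quantile normalization, a pseudocount or the 6 arrays alone, and 4 with no filter or array weights. It became 0 without heat selected replicate 2, knock-down selected replicate 1 or knock-down selected replicate 3, 2 without knock-down selected replicate 2, 3 without heat selected replicate 1 and 35 without heat selected replicate 3.

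Heat selected against cold selected females differed in 3 genes (992 at an unadjusted p under 0.05). CG15412 rose by 0.50 ± 0.07 (adjusted p = 0.0103), Cdk5 fell by 0.59 ± 0.10 (adjusted p = 0.0387) and CG15221 by 0.55 ± 0.09 (adjusted p = 0.0320). The means of CG15412, 4.53 and 4.03, lay near the filter limit of 4. Eggshell genes had a median of -0.96, gut proteases of -0.21 and maltases of 0.41. Eggshell scores on the cold selected arrays were 10.47, 10.49 and 10.72, against 9.08, 9.17 and 10.46 on the heat selected arrays. Camera called 11 lists, 0 with an estimated correlation (smallest adjusted p = 0.281 with an estimated correlation), and fry called 3. The 3 calls became 38 without heat selected replicate 3, 6 without cold selected replicate 3, and 0 without heat selected replicate 2, cold selected replicate 1 or cold selected replicate 2. A filter at 6 and the fit of the 6 arrays alone gave 0.

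Starvation selected and desiccation selected females did not differ in any called probe set, and cytosolic ribosomal proteins had a median of 0.03 between them. Limma called 0 (209 at an unadjusted p under 0.05, 1 with array weights), and camera called 1 list (adjusted p = 0.805 with an estimated correlation). Longevity selected against starvation selected females had medians of -0.16 for the tricarboxylic acid cycle, -0.14 for oxidative phosphorylation and -0.12 for muscle, with 0 calls by limma (216 at an unadjusted p under 0.05, 1 without longevity selected replicate 3). Camera called 5 lists there (adjusted p = 0.913 with an estimated correlation for each).

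**Figure D5:**
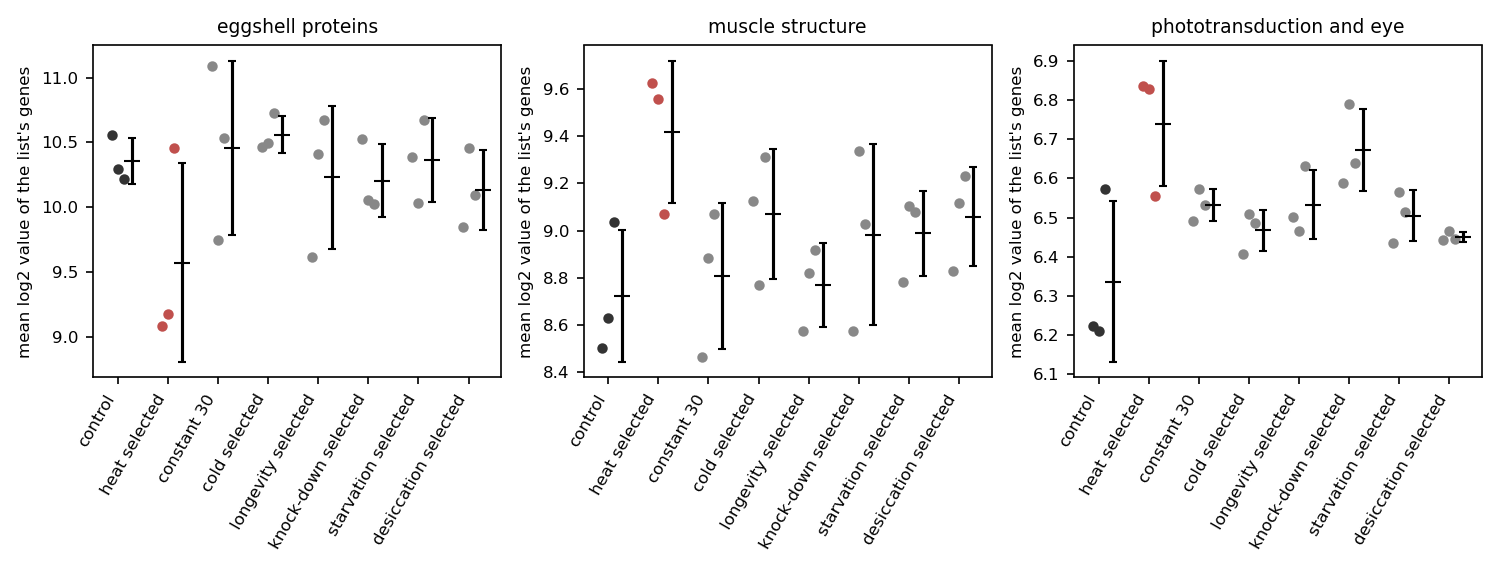
Mean log2 value of the eggshell, muscle and eye lists on each array (vertical axes) in the 8 groups (horizontal axis; points, single lines; bars, mean and SD). Heat selected replicates 1 and 2 had eggshell scores of 9.08 and 9.17, and the control arrays lay between 10.22 and 10.55.

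Some genes were called in more than 1 regime. Ctr1B, CG17752, Ank2, Ggamma30A (a G protein subunit of the eye) and OtopLb (a proton channel) rose in both heat and knock-down selected females, where 7 probe sets were called higher in both and independent lists would share 0.259, a value that leaves out the control arrays common to both. Over all tested genes, which are not independent replicates, correlations between regimes ran from 0.271 (heat selected and constant 30) to 0.729 (starvation and desiccation selected), with a median of 0.579, while unchanged groups that share the 3 controls gave 0.496 on average (0.401 to 0.596 in 100 simulations). The covariance ran from 0.0117 to 0.0296, with 0.0113 simulated on average and 9 of 21 pairs above the highest simulated value of 0.0162. The excess was highest for heat and knock-down selected, at 0.0183, and lowest for heat selected and constant 30, at 0.000317. The 3 controls cannot be split into sets of 2 or more, so part of the excess may come from the shared controls. Heat selected replicates 1 and 2 and knock-down selected replicate 2 also lay highest on the first principal component, at 18.5, 22.1 and 14.8. Whether these arrays gave the excess and the shared calls of that pair was not tested. In knock-down selected females the other probe sets of Ank2, at -0.15 and -0.10, were not called.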

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

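The tests of the control arrays, of a smaller share of ovary and of the order of the groups were chosen only after the results they concern were seen. The covariate for RNA quality was chosen after the data were seen, and its test before the result of that test. The direct comparisons of heat selected lines with other regimes are singled out because the changes against control differed by a test of the difference itself. Heat selected and constant 30 lines differed in 33 probe sets, among them srp, ND-75 and Cpr47Ef. No call was left there with the covariate for RNA quality or without heat selected replicate 2. A fit of the compared groups alone left 2. Heat selected and cold selected lines differed in 3, CG15412, Cdk5 and CG15221, and heat selected and knock-down selected lines in 1, CG15412. In either pair a fit of the compared groups alone left no call, and CG15412 lay near the filter limit of 4.

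The first pattern is that heat selected females had lower eggshell and higher muscle transcripts than control females. Against the mean of the other 6 regimes, without any control array, the eggshell score differed by -0.75 ± 0.29 and the muscle score by 0.47 ± 0.17. The smaller of these was 2.63 standard errors from 0, which argues against 3 control arrays that stand apart as the whole cause. These errors pool the spread of all groups. The heat selected lines had the widest eggshell spread (SD 0.77), so for eggshell the argument is weaker still. For muscle, heat selected replicate 3, at 9.07, lay beside the means of cold and desiccation selected lines, 9.07 and 9.06. RNA quality stays open: with the 3' minus 5' difference as a covariate, eggshell moved from -0.78 ± 0.37 to -0.85 ± 0.45 and muscle from 0.70 ± 0.22 to 0.58 ± 0.26, and the smaller of the differences was 1.89 standard errors, because the errors grew. A smaller share of whole ovary in the RNA stays open too, since the eggshell score changed by -0.67 ± 0.38 relative to the germ line score, a range that holds both no difference and the whole eggshell change. The eggshell change was -1.23 ± 0.35 without heat selected replicate 3, -0.54 ± 0.41 without heat selected replicate 1 and -0.58 ± 0.42 without heat selected replicate 2, so a response of the selected lines may be present in some lines and not in others, and selection itself remains untested as the cause.

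The second pattern is that muscle and eye lists had medians above control in all 7 regimes. The control arrays were not alike: eye scores were 6.22, 6.21 and 6.57 and muscle scores 8.50, 8.63 and 9.04 on replicates 1, 2 and 3, and replicate 3 lay above the eye means of 5 regimes and the muscle means of 4. With control as the reference, 13 of 34 lists had medians of one sign in every comparison. With heat selected as the reference there were 23, and with the other groups 3 to 7. The position of the control arrays, of replicates 1 and 2 above all, is therefore a possible explanation, and a response common to the regimes could not be separated from it because each comparison used the same control arrays.

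The third pattern is that CG2926, Scamp and CycT fell along the order in which the deposited table lists the groups. Of 9023 probe sets, 194 had a rank correlation of at least 0.9 in size with that order (154 falling, 40 rising), while random orders of the groups gave a median of 27 and as many in 1.63% of 10000 draws. The other desiccation calls, egh and CG17919 among them, are not free of this doubt: all 7 had a slope over the 24 arrays, but control is first and desiccation selected last, so a call between them nearly brings a slope and the overlap decides nothing. Drift from array to array stays open, since the slope within groups was 0.723 ± 1.09 of that between groups, too wide to decide. Batches that hold whole groups in this order cannot be told apart from the groups, and selection for desiccation resistance likewise may be the source.

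Other splits of the arrays were counted for each comparison. Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. Of these, the number that called as many probe sets as the real split was 1 for heat selected (256, highest other 6), knock-down selected (14, highest other 2) and desiccation selected (7, highest other 0) against control. It was 10 for constant 30 (0, highest other 38), cold selected (0, highest other 1), longevity selected (0, highest other 2) and starvation selected (0, highest other 1). Every split matches a real split with 0 calls, so a number of 10 carries no information here or below. Between regimes it was 1 for heat selected against constant 30 (33, highest other 0) and against cold selected (3, highest other 0), and 10 for both pairs with starvation selected (0, highest other 0). For heat selected against knock-down selected it was 2 (1, highest other 131). The split with 131 put heat selected replicates 1 and 2 with knock-down selected replicate 2, the arrays highest on the first principal component. This points to a structure of the samples other than their groups. The same arrays had the lowest 3' minus 5' differences of the 24, at 1.62, 1.34 and 1.50, with cold selected replicate 2 next at 1.63. Whether RNA quality gave this structure was not tested. The 38 came with constant 30 replicate 1 beside control replicates 1 and 2. Of 100 groupings of the 24 arrays, the real one included, 100 called as many as the mean of the regimes, as any must with 0 real calls. The highest other count there was 168, which points to a structure of the samples, whose source was not tested. For the F test 2 called as many (5, highest other 11), the real grouping among them. Random grouping thus seldom gave 5 calls, but it ignores that structure of the samples, so chance is not excluded.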

How the results depend on the processing

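The covariate for RNA quality and the comparison with the other 6 regimes were chosen after the data were seen, the covariate before its own result; the other alternatives were planned. Where a count moved, the cause was not tested. A fit of the compared groups alone has fewer arrays to estimate the spread. It also takes the spread from those groups, which can differ from that of all 8 groups. Which of these moved its counts was not tested. Of 69 called genes in 828 settings, 472 values stayed past the threshold and 356 kept their direction but not their call, 0 turning. Of 71 called lists in 1056 settings, 735 stayed called, 311 kept direction only and 10 turned sign; 260 uncalled list members in 3120 settings gave 56 calls. Probe sets above 4 on fewer than 3 arrays were tested with no filter only, while some near that limit, CG15412 among them, passed the filter. The number of arrays limits the precision of all counts.

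With no filter, heat selected against control gave 144 calls and heat against knock-down selected 4. A filter at 6 gave 2 for starvation selected, 6 for the mean of the regimes, 104 for heat selected against constant 30, and 0 for heat against knock-down selected and against cold selected. Quantile normalization gave 11 for the mean of the regimes, 71 for heat against constant 30, 0 for heat against knock-down selected and 9 for the F test. Median centring gave 4 for starvation selected and 2 for heat against knock-down selected. It moved the share of higher calls in heat against constant 30 from 54.5% (18 higher, 15 lower) to 37.8% (14 and 23), and the desiccation calls from 1 higher and 6 lower to 0 and 8, with 0 and 5 after quantile normalization. A pseudocount of 16 gave 0 for heat against knock-down selected. Trend and robust settings gave 4 for the mean of the regimes and 141 for heat against constant 30. Array weights gave 54 for knock-down selected, 177 for starvation selected, 26 for desiccation selected, 118 for the mean, 13 for heat against constant 30, 4 for heat against knock-down selected, 1 for starvation against desiccation selected and 48 for the F test. The fit of the compared groups alone gave 0 for heat, knock-down and desiccation selected against control and for heat against knock-down and cold selected, and 2 for heat against constant 30. Adjustment over the 7 comparisons together gave 12 for heat, 5 for knock-down and 2 for starvation selected. A change of at least 1 left 29 for heat selected, 3 for knock-down selected, 0 for desiccation selected, 4 for heat against constant 30 and 0 for heat against knock-down selected, heat against cold selected and the F test. The covariate left 1 call for heat selected against control and 0 against constant 30 and knock-down selected. Against the other 6 regimes, heat selected gave 998 calls (163 shared with the 256), knock-down selected 1 and desiccation selected 2.

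With the replicate number as a block, heat selected gave 410 calls, cold and longevity selected 1 each, knock-down selected 26, starvation selected 6, the mean of the regimes 15, heat against constant 30 218, heat against knock-down selected 4 and the F test 15. The labels do not say that numbers pair the lines. Of 84 pairs of arrays with the same number 34 had deviations that correlated above 0.1 (median 0.0694, and -0.0236 for different numbers), and 15 of 24 arrays correlated best with their own number, a hint from the data and not from the design. The block kept all 69 called genes, ended 1 list call and called 2 list members that were not called without it.

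Leaving out 1 array at a time gave 0 to 591 calls for heat selected, 0 to 49 for constant 30, 0 to 35 for cold, 0 to 37 for longevity, 0 to 237 for knock-down, 0 to 83 for starvation and 4 to 42 for desiccation selected against control. It gave 0 to 267 for the mean of the regimes, 0 to 430 for heat against constant 30, 0 to 35 against knock-down selected, 0 to 38 against cold selected, 0 to 1 for longevity against starvation selected and 2 to 78 for the F test. The highest counts came without control replicate 3 or without heat selected replicate 3, except for longevity against starvation selected, where it came without longevity selected replicate 3. The median correlation of regimes was 0.724 without control replicate 3 and otherwise between 0.517 and 0.589.

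List calls against control with an estimated correlation numbered 0 in all 7 regimes, and fry gave 3 for heat selected and 0 for the others. A filter at 6 gave 7 for constant 30 and 6 for longevity selected, and no filter 12 for desiccation selected. With 1 array left out, the fewest list calls were 4 for constant 30, 5 for cold and longevity, 6 for knock-down, 7 for starvation and 3 for desiccation selected, which also had 11. List medians that turned sign were neuronal markers with no filter (-0.040 in constant 30, -0.00518 in starvation selected), the vacuolar ATPase list (-0.00176 in starvation selected with no filter, and with 1 array left out in longevity selected from -0.000939 without control replicate 1 to 0.043 without longevity selected replicate 2), glutathione S-transferases (-0.018 in knock-down and -0.025 in starvation selected with no filter, and in knock-down selected from -0.027 without replicate 1 to 0.057 without replicate 2), lipid genes in starvation selected (-0.00331 without control replicate 1, -0.032 without starvation selected replicate 3, and up to 0.089 without replicate 1) and lysozymes in desiccation selected (from -0.000453 without replicate 3 to 0.451 without replicate 1).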

Other observations

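The relation of yolk with eggshell scores and of muscle with eye scores was tested only after the lists had been examined. A hypothesis of a shift between eggshell and muscle transcripts that varies among lines of every regime was tested on the deviations of the 24 arrays from their group means. The correlation was -0.335 (permutation p = 0.208, rho -0.299, permutation p = 0.241) and -0.131 without the 2 arrays farthest from the median, so the hypothesis was not borne out. In the same family of 3 relations with 100000 permutations within groups, yolk and eggshell scores correlated at 0.873 (permutation p = 9e-05, adjusted 0.00027; rho 0.857, permutation p = 0.00025, adjusted 0.00075) and at 0.784 without the 2 farthest arrays. Muscle and eye scores correlated at 0.688 (permutation p = 0.00304, adjusted 0.00456; rho 0.743, permutation p = 0.00168, adjusted 0.00252) and at 0.615 without them.

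Some genes varied widely between lines of a group. The antimicrobial peptide genes Mtk and DptB had SDs within groups of 2.38 and 1.95. Mtk ran from 3.31 on cold selected replicate 2 to 12.42 on constant 30 replicate 3, and DptB from 4.63 on heat selected replicate 1 to 11.96 on constant 30 replicate 3. Acp1 and Acp65Aa, adult cuticle proteins that the male accessory gland list took in through their symbols, were at 10.99 and 7.78 on heat selected replicate 1. Eggshell genes had a median SD within groups of 0.53, antimicrobial peptides 0.38 and muscle genes 0.29, at percentile 100 of 10000 random lists matched on mean expression. Cytosolic ribosomal proteins, at 0.07, and mitochondrial ribosomal proteins, at 0.09, lay at percentile 0.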
